A study of Homo sapiens with 4 samples.

How the data were processed

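RNA from MCC26 cells, an established line of Merkel cell carcinoma (a neuroendocrine cancer of the skin), was measured on 4 one-colour human expression arrays with probes of 60 bases. Per the labels' protocols, cells at about 30 percent confluence were transfected with 5 nM of a synthetic miR-375 mimic or of a negative control mimic with a cationic lipid, and total RNA was taken 72 h later, amplified and labelled with Cy3. There were 2 arrays per group, numbered 1 and 2 in each. The labels do not say that the repeats were separate cultures, so p-values measure the spread between these samples, which may be technical.

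The deposited scanner files hold spot intensity values. Per the file headers and the submitters' processing notes, they were made with Agilent Feature Extraction 10.5.1.1, on a probe design placed on the hg18 (NCBI36) human genome. The processed signal in the deposited files is intensity after background subtraction and spatial detrending, with surrogate values for low signals, and it was not scaled between arrays. Mean spot intensity and median local background intensity were also deposited. The authors' deposited value table is on a log2 scale (5.942 to 18.652 over 28376 probes), and how it was normalized is not given in the sources used here. Its columns had medians of 8.469 and 8.474 for the miR-375 mimic arrays and of 8.473 and 8.468 for the control arrays. Each column correlated across probes with the log2 mean spot intensity of the same array (lowest Pearson r = 0.998), which leaves its between-array scaling unknown and points to values that keep the background. Values that keep the background understate changes of dim probes.

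The tested value was log2 of the processed signal minus log2 of each array's 75th percentile of it. Those percentiles were 674.8 and 778.5 for miR-375 mimic arrays 1 and 2, and 748.5 and 731.7 for control arrays 1 and 2. Control spots and spots flagged as outliers by the scanner software were left out, and spots of a probe were averaged. This left 40986 of 41000 probes measured on all 4 arrays. Probes well above background numbered 29411 and 30274 on the mimic arrays and 29668 and 29247 on the control arrays, and 0 probes were saturated. The 29512 probes well above background on both arrays of at least 1 group were tested. A probe below background on both arrays of a group has only a bound there. Its difference is given as "at least N-fold", with the lowest signal among probes well above background on an array as the floor. The p-value of such a probe is that of its fitted difference and does not test the bound. The number of arrays limits the precision.

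Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the group as the only term, and p-values were adjusted with the Benjamini-Hochberg method over the tested probes at a threshold of 0.05. A gene was represented by its brightest tested probe. Gene names came from a reference table of the GRCh38.p14 assembly, used for names only: 25393 probes matched by accession, 2515 by symbol and 789 by an older symbol, and 12303 kept the name in the file. Coordinates are those of the probes in the files (hg18). The genes named were fixed by rule: the 12 largest fitted log2 fold changes in each direction, bounded ones included, among genes past the threshold with the same sign in both same-numbered pairs, groups that did not overlap and a named, unsaturated probe, then NOTCH2, RBPJ, YAP1 and PDPK1, then up to 4 members with the smallest adjusted p of each list. Some genes that the rule names are not reported here. Members of a list beyond those are given as examples of its count and were chosen after their values were seen. The 21 gene lists were fixed from textbook knowledge. The rule, the 21 lists, the tests of the comparison and of these lists, and the alternatives below were set before the data were examined, while tests and rankings said to be added or chosen later were not. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists, and again with camera at an estimated correlation and with fry. With an estimated correlation camera tests on the few residual degrees of freedom that 4 arrays leave, so its p-values rise even where the estimate is low. Where the estimate is well above the preset, the p-value at the preset can be too small. Camera compares members with the other genes, while fry asks whether members changed at all, so they answer different questions.

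On simulated data with the means of the 29512 probes and the fitted prior spread, where 200 probes changed by known amounts, limma recovered 1.49% of changes of 1 on the log2 scale, 79.1% of changes of 2 and 97.0% of changes of 3, and 5.6% of its calls were false. Recovery depends on the share of probes that change. In the data 1714 probes passed, so these rates do not give the recovery here. The camera and seed tests were also tested on simulated data. Alternatives were quantile normalization, median scaling, normexp background correction (offset 50), 2 other filters on dim probes, the authors' deposited log2 table, the replicate number as a block, a trended and robust prior, leaving out each array, and the mean of a gene's probes. All 4 arrays were on 1 slide and in 1 scan session, so no block for slide was fitted. The planned test of miR-375 sites in 3' UTRs was not run, because no transcript sequences were used here. A test of the 60 probe bases, run with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, was added after the files were seen. The array does not measure mature miR-375, so the transfection itself was not checked.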

Results

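The data were 4 whole-genome expression arrays of MCC26 cells, a Merkel cell carcinoma line, 72 h after transfection with a miR-375 mimic (n = 2 arrays) or a negative control mimic (n = 2 arrays), each at 5 nM. miR-375 is a microRNA abundant in neuroendocrine cells. Between 71.3% and 73.9% of the probes on an array were well above background. Across probes, arrays of the same group correlated at r = 0.993 (mimic) and r = 0.991 (control), and arrays of different groups at r = 0.978 to 0.984. Levels below are log2 signals relative to the array's 75th percentile, given as mean ± SD with n = 2, and log2 fold changes are mimic over control with the standard error (SE) of the limma fit.

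The comparison of the 2 mimics asks which transcripts differ when miR-375 is supplied. SCG3, PCSK1, SCG2, CHGB and STMN3, all on the fixed list of neuroendocrine and Merkel cell markers, were among the 12 largest rises of genes measured in both groups, a ranking made after the values were seen. SYT4, a synaptotagmin of secretory vesicles, was at -1.25 ± 0.27 with the mimic and -5.73 ± 0.17 in the control, a 22.2-fold rise (log2 fold change 4.47, SE 0.20, adjusted p = 0.00306). SCG3, a secretogranin of dense-core granules, rose 21.3-fold (log2 fold change 4.41, SE 0.18), and SCG2 and CHGB, granins of the same granules, rose 9.91-fold and 9.59-fold. PCSK1, a prohormone convertase, rose 11.1-fold. CPLX1, a complexin that acts in vesicle fusion, rose 13.4-fold, and AP3B2, a neuronal adaptor subunit, 12.5-fold. CKMT1A, a mitochondrial creatine kinase with a near-identical copy, CKMT1B, that the probe cannot be assumed to exclude, rose 11.5-fold. TMEM145 rose 17.9-fold and TMEM121B 10.8-fold. KCNC1, a voltage-gated potassium channel, and RAB3C, a vesicle GTPase, were not well above background on either control array. They were at least 12.5-fold and at least 3.30-fold higher with the mimic, bounds that give them no rank. Their limma adjusted p-values (0.0299 and 0.00306) belong to the fitted log2 fold changes of 4.81 and 3.68. Those use control values under the floor, so the p-values do not test the bounds. With normexp background correction the log2 fold changes were smaller, at 2.27 for SYT4, 2.40 for SCG3, 2.31 for CPLX1, 1.82 for TMEM121B, 2.46 for AP3B2, 2.07 for CHGB, 2.499 for PCSK1, 3.39 for TMEM145, 1.54 for KCNC1 and 0.59 for RAB3C, the last 2 under their bounds, which hold for the processed signal. In the authors' deposited value table they were 2.16 for SYT4, 2.30 for SCG3, 2.20 for CPLX1, 1.72 for TMEM121B, 2.36 for AP3B2, 1.98 for CHGB, 2.41 for PCSK1 and 3.33 for TMEM145.

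Among the falls, TNNT2, cardiac troponin T, was at -5.85 ± 0.39 with the mimic and -2.13 ± 0.14 in the control (log2 fold change -3.72, SE 0.23, adjusted p = 0.00466), and was well above background on 1 of the 2 mimic arrays. SCARNA17, a small Cajal body RNA, had a log2 fold change of -3.62 (SE 0.28) and POC1B, a centriole protein, of -2.85 (SE 0.17). MAT2B, the regulatory subunit of methionine adenosyltransferase, was at -0.53 ± 0.20 against 2.09 ± 0.04 (log2 fold change -2.63, SE 0.17, adjusted p = 0.0052), and its other probe gave -2.58. PLEKHS1 had a log2 fold change of -2.71, OLR1, a receptor for oxidized lipoprotein, of -2.63, and ITIH3 of -2.39. In the mimic arrays PROK1, SELENBP1, CIMIP1, TEX11 and MATN3 were not well above background, and they were lower by at least 4.44-fold, 3.66-fold, 3.48-fold, 1.85-fold and 1.80-fold, bounds that give them no rank. Of these named rises and falls, CHGB, ITIH3, KCNC1, OLR1, PLEKHS1 and TEX11 did not pass without mimic array 1, ITIH3, KCNC1, OLR1 and PLEKHS1 without mimic array 2, and ITIH3 and SELENBP1 without control array 2 (adjusted p = 0.0505 to 0.189). Without the filter on dim probes AP3B2, CHGB, KCNC1, TNNT2, SCARNA17, POC1B, MAT2B, PLEKHS1, OLR1, ITIH3, PROK1, SELENBP1 and TEX11 did not pass (0.0532 to 0.111), and with normexp MATN3 and TEX11 did not (0.240 and 0.227). Log2 fold changes with normexp were smaller, at -1.59 for TNNT2, PLEKHS1 and OLR1 each, -2.50 for SCARNA17, -1.70 for ITIH3, -0.70 for PROK1, -0.64 for CIMIP1, -0.57 for SELENBP1 and -0.27 for MATN3 and TEX11 each, the last 5 genes under their bounds, and the authors' deposited value table gave -1.58 for TNNT2, -1.60 for PLEKHS1 and OLR1 each, -1.72 for ITIH3 and -2.48 for SCARNA17.

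**Figure D1:**
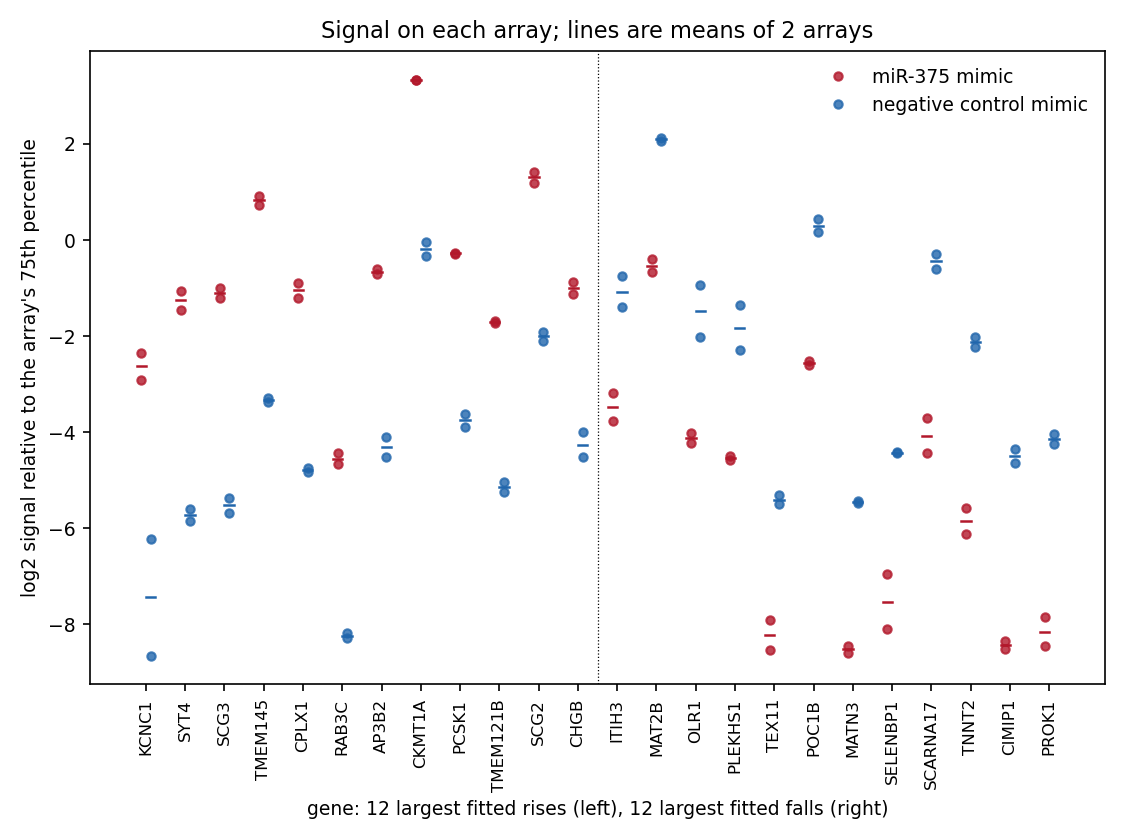
Log2 signal relative to the array's 75th percentile (vertical axis) on each of the 4 arrays for the 12 largest fitted rises and the 12 largest fitted falls (horizontal axis), with red points for the miR-375 mimic, blue points for the negative control mimic and a line at each mean of 2 arrays. The groups do not overlap for any of these genes, which the choice of genes required, and the 2 arrays of KCNC1 in the control lie farthest apart.

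In all, 1714 of 29512 tested probes passed the threshold, 1078 higher and 636 lower with the mimic, and 6823 had an unadjusted p under 0.05. Of the 1714, 191 were not well above background in the dimmer group. With these at their bound, 1077 differed by at least 2-fold (712 higher, 365 lower), and 76 were at least 4-fold higher and 42 at least 4-fold lower. By fitted values, 1158 differed by at least 2-fold (777 higher, 381 lower). Among genes with a reference name, 979 of 14812 passed, 642 higher and 337 lower. The 62.9% share of higher calls depended on the processing. It was 53.3% with quantile normalization, 54.7% with median scaling, 54.0% with normexp and 49.2% (797 higher, 824 lower) in the authors' deposited value table. Over probes well above background on all 4 arrays it was 59.9%, with a trended and robust prior 58.7% and with the replicate block 63.2%. Without the filter on dim probes it was 82.4% of 17 calls. Groups did not overlap for 54.0% of the tested probes. The 33.3% that chance gives is an average over the 3 splits of 4 arrays into 2 and 2. Effects shared by many probes can raise the share of 1 split, and the other splits were not computed. The excess is therefore not a test of the mimic. The count rested on the arrays kept: it was 98 without miR-375 mimic array 1, 201 without mimic array 2, 1134 without control array 1 and 630 without control array 2, in fits that assume that the lone array varies like the other group, and 17 when probes below background were not filtered out.

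**Figure D2:**
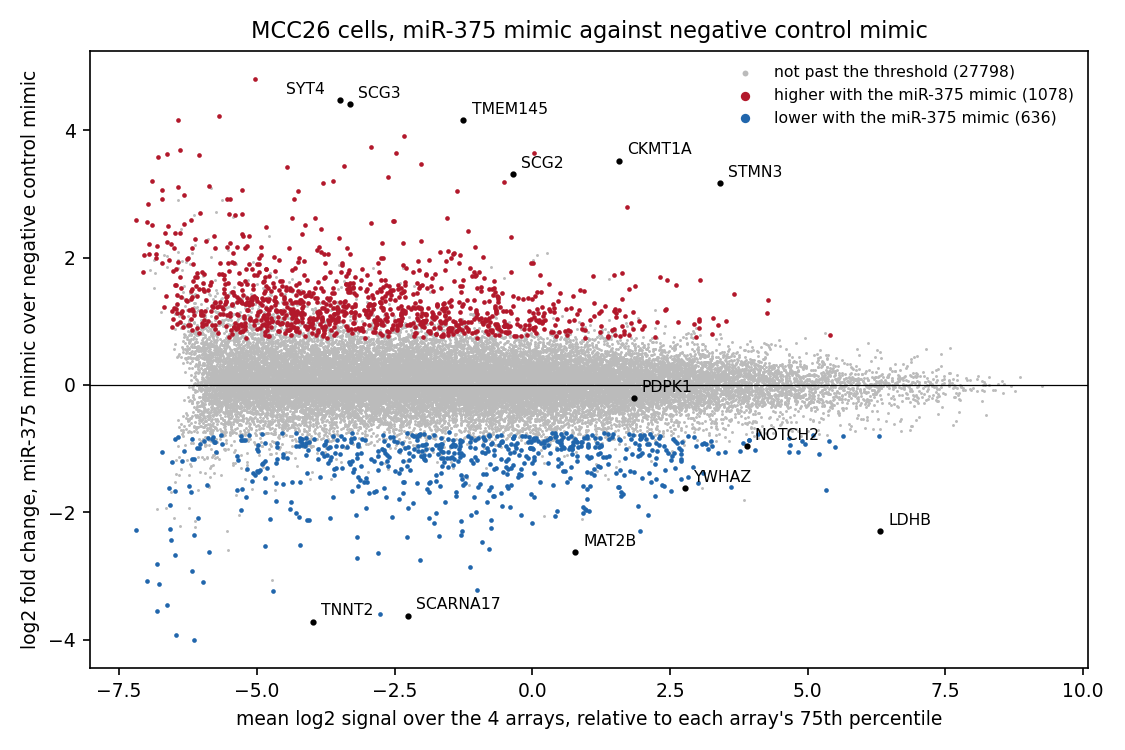
Log2 fold change of the miR-375 mimic over the negative control mimic (vertical axis) against the mean log2 signal over the 4 arrays, relative to each array's 75th percentile (horizontal axis), with 1 point per tested probe. Red marks the 1078 probes higher with the mimic, blue the 636 lower and grey those not past the threshold, and black points are named genes.

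Genes reported as miR-375 targets in other work fell as a group. Of 47 tested, 13 fell and 0 rose, and 23 fell when adjusted over the list alone (0 rose). The median log2 fold change was -0.53 (camera adjusted p = 1.35e-12), and 41 of 47 were below 0. The list was lost with an estimated correlation (adjusted p = 0.325) and kept by fry (adjusted p = 0.0315). LDHB, a lactate dehydrogenase subunit, went from 7.47 ± 0.01 to 5.17 ± 0.09 (log2 fold change -2.30, SE 0.15, adjusted p = 0.00546). YWHAZ, a 14-3-3 protein, had a log2 fold change of -1.62 (SE 0.20, and -1.33 to -1.72 over its 7 probes), and SEC23A, a coat protein of secretory transport, of -1.52 (SE 0.16). Of the genes named in advance, NOTCH2, a Notch receptor, fell by 0.96 on the log2 scale (SE 0.15, adjusted p = 0.0299, probe at chromosome 1, 120256381 to 120256440 on hg18). RBPJ, the DNA-binding partner of Notch, fell by 0.75 (SE 0.15, adjusted p = 0.0484, chromosome 4, 26041784 to 26041843), and 1 of its 2 other probes did not pass. YAP1, a transcriptional co-activator, fell by 0.83 (SE 0.16, adjusted p = 0.0474, chromosome 11, 101605794 to 101605853), and its other probe did not pass. PDPK1, a kinase that activates AKT, had a log2 fold change of -0.20 (SE 0.15, adjusted p = 0.488). With any array left out, NOTCH2 (adjusted p = 0.0664 to 0.197), RBPJ (0.0882 to 0.293) and YAP1 (0.0662 to 0.289) did not pass, while LDHB was lost without mimic array 1 (0.0524), SEC23A without mimic array 1 (0.120) or 2 (0.0869) and YWHAZ without mimic array 1 (0.150), mimic array 2 (0.0869) or control array 2 (0.0507). With quantile normalization the calls of RBPJ (adjusted p = 0.0541) and YAP1 (0.0534) were lost, and without the filter on dim probes those of all 6 called genes named here (0.0567 to 0.131). Without that filter their log2 fold changes were unchanged, and only the number of probes and the fitted prior differed. NOTCH2 and RBPJ may have been reported from these same arrays, so their direction is not independent evidence.

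Neuroendocrine and Merkel cell markers rose as a group. Of 35 tested, 11 rose and 1 fell, and 18 rose and 3 fell when adjusted over the list alone. The median log2 fold change was 0.64 (camera adjusted p = 1.34e-05), and the call was lost with an estimated correlation (adjusted p = 0.325) and kept by fry (adjusted p = 0.0193). Besides SCG3, RAB3C, PCSK1, SCG2 and CHGB, the risers included STMN3, a stathmin of neurons (1.83 ± 0.11 to 4.99 ± 0.10, log2 fold change 3.17, SE 0.16), ELAVL3, a neuronal RNA-binding protein (at least 4.60-fold, not well above background in the control; log2 fold change 0.64 with normexp), STMN2 (1.76, SE 0.19) and ENO2, neuron-specific enolase (1.53, SE 0.18). KRT8, a keratin of simple epithelia and Merkel cells, fell by 1.34 (SE 0.18). Log2 fold changes were 0.21 (SE 0.23) for CHGA, -0.10 (SE 0.15) for UCHL1 and -0.82 (SE 0.55) for INSM1, none past the threshold. The median was smaller with normexp background correction (0.26), without the filter on dim probes (0.33), over probes well above background on all 4 arrays (0.42) and in the authors' deposited value table (0.17), with adjusted p-values of 2.88e-05, 0.000255, 0.000403 and 0.00109. Without mimic array 1 the calls of CHGB, ELAVL3, STMN2, ENO2 and KRT8 were lost (0.0506 to 0.167), as were those of STMN2, ENO2 and KRT8 without mimic array 2 (0.0846 to 0.107), of KRT8 without control array 2 (0.0578) and of all 5 without the filter on dim probes (0.0658 to 0.0892).

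Notch pathway genes did not shift as a group (median 0.10, camera adjusted p = 0.982), and members moved in both directions. Of 41 tested, 4 fell and 3 rose (4 and 5 adjusted over the list alone). With NOTCH2 and RBPJ, HES5, a Notch-induced repressor, fell by 1.19 (SE 0.21, adjusted p = 0.0366) and NUMB, a Notch inhibitor, by 0.81 (SE 0.15, adjusted p = 0.0415). DNER, a noncanonical ligand, rose by 1.45 on the log2 scale (SE 0.28), DTX1, a ubiquitin ligase of the pathway, by 0.90 (SE 0.15, adjusted p = 0.0341) and DLL3, an inhibitory ligand, by 0.77 (SE 0.15). With any array left out NUMB, DTX1 and DLL3 did not pass (adjusted p = 0.0687 to 0.281), and HES5 passed only without control array 1 and DNER only without control array 2 (0.0542 to 0.243 otherwise). None of these 5 passed without the filter on dim probes (0.109 to 0.135), with quantile normalization DNER (0.0623) and DLL3 (0.061) did not, and with median scaling DLL3 (0.0557) did not. In the authors' deposited value table DNER was at 0.95, DTX1 at 0.58 and DLL3 at 0.50.

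YAP/TEAD target genes were lower as a group (4 of 25 fell and 0 rose, 4 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.0158). The list did not pass with an estimated correlation (adjusted p = 0.819) or by fry (adjusted p = 0.293). NT5E, an ectonucleotidase, fell by 1.37 (SE 0.15), CRIM1 by 1.32 (SE 0.15), WWC1, itself an upstream regulator of the pathway, by 0.92 (SE 0.16) and FRMD6 by 0.83 (SE 0.16). Other probes did not pass, at 0.10 and -0.48 for NT5E, -0.58 for CRIM1 and -0.37 for FRMD6. None of the 4 genes passed without mimic array 1 or 2 (adjusted p = 0.0866 to 0.225) or without the filter on dim probes (0.0826 to 0.124), nor WWC1 and FRMD6 without a control array (0.0673 to 0.116). Cholesterol biosynthesis genes had a median of -0.28 (camera adjusted p = 0.0158) with 0 of 24 members called, and that list did not pass with an estimated correlation (adjusted p = 0.819) or by fry (adjusted p = 0.698). Its estimated correlation was 0.829, so the same limit holds for its p-value at the preset. Both lists were lost with quantile normalization (0.0773 for each). YAP/TEAD targets were also lost without control array 2 (0.299), and the cholesterol median was 0.048 without control array 1 (adjusted p = 0.815).

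None of the other 16 lists shifted by camera, with adjusted p-values of at least 0.108. Among markers of other cell types, 2 of 16 fibroblast markers fell (PDGFRA by 1.31, SE 0.22, and PDGFRB by 0.77, SE 0.15) with a median of -0.16 (camera adjusted p = 0.108). Of 10 keratinocyte markers KRT17 rose (0.91, SE 0.15), of 7 melanocyte markers MC1R rose (0.88, SE 0.15), and 0 of 8 leukocyte and B cell markers and 0 of 5 endothelial markers passed. Of 32 interferon-stimulated genes, which can answer to transfected RNA, GBP1 fell by 0.92 (SE 0.15) and 0 rose, with OASL at 1.37 (adjusted p = 0.05003), IFIT1 at -0.69 (adjusted p = 0.0643) and IFI27 at 0.68 (adjusted p = 0.0823). The interferon median was 0.19 with 22 of 32 above 0 (camera adjusted p = 0.357), and OASL passed with median scaling (0.0424), over probes well above background on all 4 arrays (0.0389) and with a trended and robust prior (0.0353) but not with normexp, with quantile normalization or with an array left out. IFIT1 passed with normexp (0.012), in the authors' deposited value table (0.026) and with that prior (0.0268), and IFI27 with normexp (0.0422). The integrated stress and unfolded protein response (0 of 24), small RNA machinery (0 of 13) and cytosolic ribosomal proteins (0 of 25) had no called member in the main fit. With normexp DDIT3 (0.53), HERPUD1 (-0.74) and PSAT1 (-0.70) of the stress list passed (limma adjusted p = 0.027 to 0.0401), as did the brightest RPS19 probe (-0.71, adjusted p = 0.0159). With the trended and robust prior HERPUD1 (0.0453), PSAT1 (0.0358) and that RPS19 probe (0.018) passed. The RPS19 probe also passed with median scaling (0.0449), over probes well above background on all 4 arrays (0.0483) and in the authors' deposited value table (0.0264). The other probes of PDGFRA (-0.89) and MC1R (0.80) did not pass, and a less bright probe of RPS19 did (-0.84, adjusted p = 0.0437). With any array left out PDGFRB, KRT17, MC1R and GBP1 did not pass (adjusted p = 0.0647 to 0.266), PDGFRA passed only without control array 2 (0.0608 to 0.183 otherwise), and none of the 5 passed without the filter on dim probes (0.104 to 0.124), nor KRT17 in the authors' deposited value table (0.44, adjusted p = 0.0671). Adjusted over the list alone, 2 fibroblast markers fell and 0 rose, 2 keratinocyte markers rose and 1 fell, 2 melanocyte markers rose and 0 fell, 2 endothelial markers rose and 1 fell, and 1 interferon-stimulated gene rose and 1 fell, with 0 in the leukocyte, stress response, small RNA and ribosomal lists.

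Of 40 cell cycle genes, CCNE2, cyclin E2, rose by 1.17 on the log2 scale (SE 0.17), while TYMS, thymidylate synthase, fell by 1.07 (SE 0.17) and CENPF by 0.79 (SE 0.15). Of 25 cell cycle inhibitors and p53 targets, 3 rose: TP53I3 (1.19, SE 0.17), CDKN2D (0.92, SE 0.18) and SESN1 (0.83, SE 0.16). Of 18 epithelial markers EPCAM (1.18, SE 0.19) and CLDN3 (0.96, SE 0.17) rose and ELF3 fell by 1.27 (SE 0.19). Of 18 mesenchymal markers TNC rose (1.02, SE 0.18). Of 21 WNT signaling genes RNF43 rose (1.28, SE 0.22), and SFRP1, a secreted WNT inhibitor, fell by 1.38 (SE 0.16) and TCF7L1 by 0.84 (SE 0.16). The mesenchymal median was -0.011 and its mean 0.055, and the WNT median was 0.074 and its mean 0.046 although camera ranked it downward. Of 18 neuronal differentiation and axon genes NRCAM was at least 3.34-fold higher (not well above background in the control), and L1CAM and DPYSL3 fell by 1.23 (SE 0.22) and 0.81 (SE 0.16). Other probes of CLDN3 (0.02), CENPF (-0.73), SESN1 (0.81), DPYSL3 (-0.55) and L1CAM did not pass. With any array left out CCNE2, TYMS, CENPF, TP53I3, CDKN2D, SESN1, CLDN3, TNC, TCF7L1, L1CAM and DPYSL3 did not pass (adjusted p = 0.0552 to 0.286). EPCAM, RNF43 and NRCAM passed only without control array 1, ELF3 only without control array 2 and SFRP1 only without control array 1 or 2 (adjusted p up to 0.222 otherwise), and none of the genes named so far in these lists passed without the filter on dim probes (0.083 to 0.128). CENPF, CDKN2D, SESN1, CLDN3 and TCF7L1 were lost with quantile normalization (0.0503 to 0.0553), L1CAM (-0.36, adjusted p = 0.110) and NRCAM (0.42, adjusted p = 0.0962) with normexp, and CCNE2 (0.53, adjusted p = 0.0511) in the authors' deposited value table, where CLDN3 was at 0.58. LDHB was the only called member of 24 glycolysis and hypoxia genes, and that list passed by fry (adjusted p = 0.0118) but not by camera (adjusted p = 0.158). Adjusted over the list alone, the members that rose and fell numbered 1 and 3 for the cell cycle, 3 and 0 for its inhibitors and p53 targets, 5 and 2 for epithelial markers, 1 and 0 for mesenchymal markers, 3 and 3 for WNT signaling, 3 and 2 for neuronal differentiation, and 0 and 1 for glycolysis and hypoxia.

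**Figure D3:**
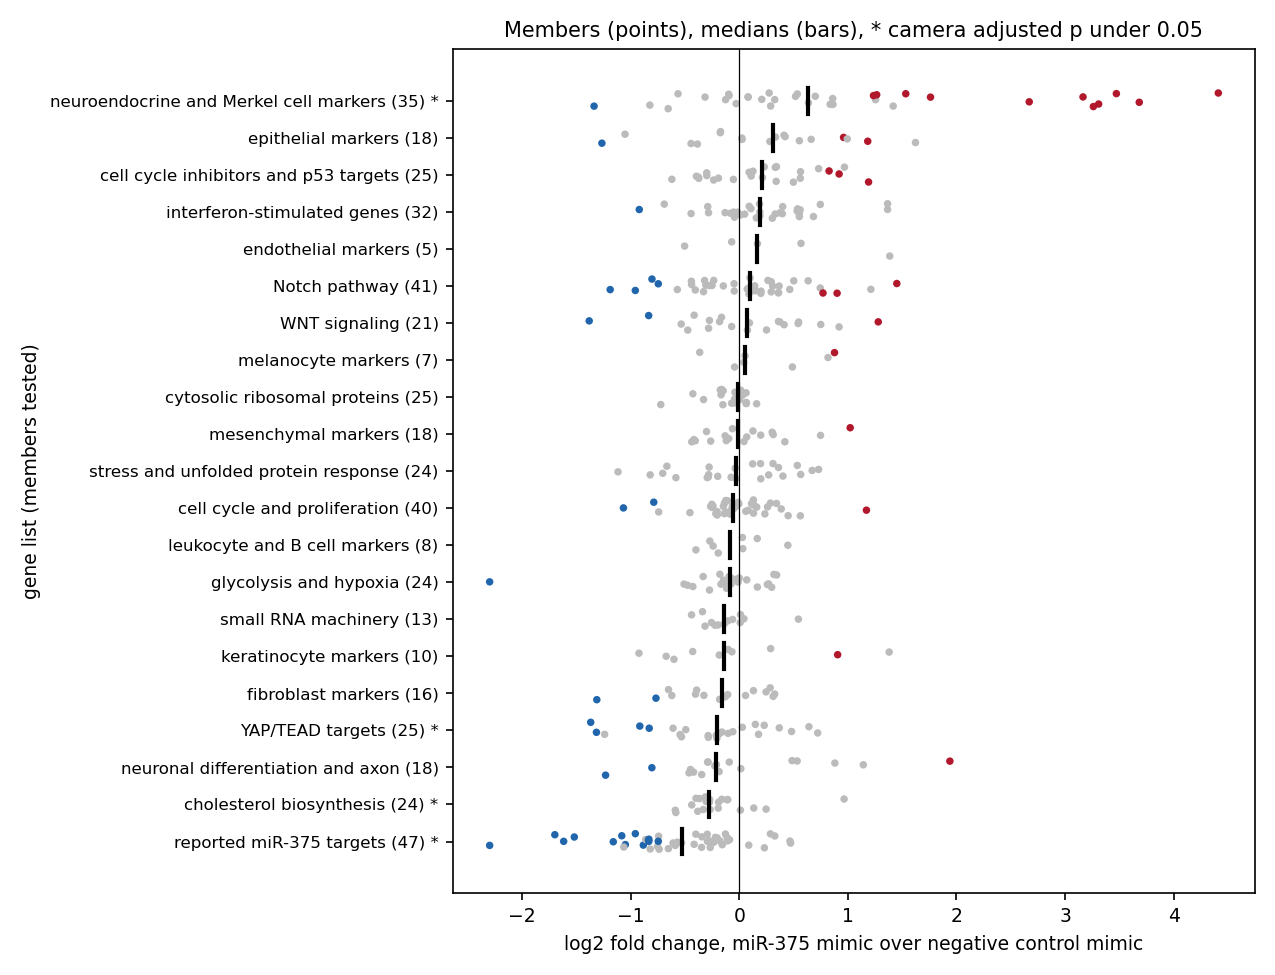
Log2 fold change of the miR-375 mimic over the negative control mimic (horizontal axis) for each tested member of the 21 gene lists (vertical axis, number tested in parentheses), with red for members that rose, blue for those that fell, grey for the rest, a black bar at each median and a star where camera passed. Neuroendocrine and Merkel cell markers have the highest median (0.64) and reported miR-375 targets the lowest (-0.53).

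The 2 repeats were compared through the log2 ratios of the same-numbered arrays, which share no array. Here each name counted as a gene, also a name kept from the file, and 14812 of the 21410 had a reference name. Across these 21410 genes, which are not independent replicates, the ratios correlated at Pearson r = 0.678 and Spearman rho = 0.602, and 71.1% of genes had the same sign in both. The median absolute log2 difference between arrays of a group was 0.167 for the mimic and 0.215 for the control.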

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

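Each of the 1714 probes past the threshold kept its sign with quantile normalization and normexp, as did the 1470 in the authors' value table, but the counts moved. Without the filter on dim probes 17 probes passed, 17 of them at least 2-fold by fitted values, out of 40986 tested. Probes with at least a 2-fold difference numbered 429 with normexp correction and 375 in the authors' value table. Leaving out an array gave 98 to 1134 probes past the threshold, and 98 to 1134 with at least a 2-fold difference. The replicate block, for samples that share only a number (the correlation of same-numbered deviations was 0.26), gave 2171 calls against 1714 and kept 59 of 60 named genes, all but RBPJ (adjusted p = 0.0501). OASL, not called in the main fit, passed with the block (adjusted p = 0.0196). Of 60 named genes past the threshold, 53 remained with quantile normalization, 56 with normexp, 12 without the dim filter and 19 to 36 with an array left out. Lists past the camera threshold numbered 2 with quantile normalization and 0 with an estimated correlation against 4, and fry's mixed test passed 18. Across the alternatives, left-out arrays included, 4 results of lists not called in the main fit passed camera. The reported targets and the neuroendocrine markers passed camera under each rescaling, filter, block, left-out array and mean of probes; the cause of the changes was not tested.

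The correlation of the 2 repeats was 0.702 with normexp, 0.694 in the authors' table and 0.383 without the dim filter. Lists near 0 that were not called changed sign: mesenchymal markers at 0.012 (quantile), 0.044 (no dim filter) and 0.028 (authors' table), stress response at 0.0027 and ribosomal proteins at 0.023 (quantile) and 0.0095 (authors' table), melanocyte markers at -0.014 (median scaling), leukocyte markers at 0.025 (no dim filter) and endothelial markers at -0.071 (only probes above background on all 4 arrays). With an array left out, medians ran from -0.056 to 0.018 for mesenchymal markers, -0.050 to 0.12 for stress response, -0.11 to 0.046 for ribosomal proteins, -0.20 to 0.027 for leukocyte markers, -0.096 to 0.013 for cell cycle genes, -0.37 to 0.012 for keratinocyte markers and -0.58 to 0.048 for cholesterol biosynthesis. The seed-site test in 3' UTRs and its alternatives, and the slide block, were not run.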

Other observations

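The tests on muscle genes, REST, dim probes and cell share were chosen after the results were seen, while those on the seed match were written before their result was seen but after the files had been. Muscle contractile genes, a textbook list of 68 put together after TNNT2 was seen, held 49 tested members, of which 10 fell and 3 rose. With TNNT2, the falls included MYL1 (log2 fold change -2.04, SE 0.18), NEXN (-1.75, SE 0.22), CNN1 (-1.47, SE 0.15) and JPH2 (-1.37, SE 0.20), and the rises TNNT1 (1.30, SE 0.20), PDLIM3 (0.98, SE 0.17) and TNNI3 (0.98, SE 0.15). Without mimic array 1 none of these but TNNT2 passed (adjusted p = 0.0861 to 0.250), nor without mimic array 2 any but TNNT2 and MYL1 (0.0831 to 0.162), without control array 1 PDLIM3 and TNNI3 (0.052 and 0.0653), or without control array 2 NEXN, JPH2, TNNT1, PDLIM3 and TNNI3 (0.0512 to 0.102). None of the 8 passed without the filter on dim probes (0.0567 to 0.118), and with normexp the log2 fold changes of TNNT2 and TNNI3 were -1.59 and 0.56. Without the 3 members whose fitted fall was at least 4-fold (TNNT2, MYL1 and MYOZ2, the last not well above background with the mimic and lower by at least 1.18-fold), camera still gave p = 0.00529 downward (0.0784 with an estimated correlation). The 46 kept members include some well above background in only 1 group, such as MYL4 (control only, -1.57, and -0.31 with normexp) and JPH1 (mimic only, 0.78). This class test was not run with another normalization or filter. A fall of contractile genes as a class may hold, although members also rose. A QKI probe, chosen after its value was seen, fell by 3.60 (SE 0.16, adjusted p = 0.00306), while the brightest QKI probe was at -1.06 (SE 0.24, adjusted p = 0.0665).

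The first pattern is the rise of neuroendocrine and secretory genes. Over the 30 members well above background on all 4 arrays the median was still 0.42, which argues against signal near background as the whole of it. Of 21 markers under the 75th percentile in the control and well above background, 10 had a 95% interval wholly below a log2 fold change of 1, while 9 markers of the list lay wholly above it. This argues only against a higher share of neuroendocrine cells that alone carry all these markers. A marker that other cells also express would rise less, so other changes in cell share are not excluded. Weaker repression by REST, a repressor of neuronal genes, stays open as a hypothesis: REST was lower by its brightest probe (-0.71, SE 0.17, adjusted p = 0.0765, so not past the threshold; -0.41 by its other probe), and 31 textbook REST targets outside the list were higher (11 rose and 1 fell, camera p = 0.00061, 0.0597 with an estimated correlation). For the 29 of these targets outside the 12 largest fitted rises, limma's camera gave a p of 0.00898 (0.0979 with an estimated correlation) at a median of 0.19. Some textbook REST targets (CRH, SCN3B, SNAP91 and UNC13A) were well above background only with the mimic. Members that pass the filter this way lean upward, and the REST targets were not tested over probes well above background on all 4 arrays. The median was 0.55 over all 31 and 0.70 over 25 markers not on the REST list, a difference that was not tested, so a role of REST in particular is not shown.

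The second pattern is the set of genes that fell, of which some may pair directly with the miR-375 seed, taken from the mature sequence as textbook knowledge gives it. The 138 genes (names kept from the file included) whose brightest probe holds a 7-base match to the seed had a median log2 fold change lower by 0.16 than the 21014 without a 6-base match (difference -0.161, two-sided permutation test within 10 bins of GC content, 100000 resamples, p = 3e-05). The 95% interval of the difference, -0.216 to -0.121, came from a bootstrap of the 138 genes alone. It held the other median fixed and used no GC bins. Below 0 were 64.5% against 43.3%, while the reverse complement of the match gave a difference of 0.046 (permutation p = 0.141). Of the 29 other orders of the same bases, 0 ranked as low as the 6-base site, which argues against base composition, though the site ranked 2 of 4087 hexamers among GC-rich ones, so GC content may carry a trend of its own. The difference was -0.155 over all tested probes and -0.103 in the authors' value table, both chosen after the data were seen. Genes are not independent replicates, so the permutation p and the interval describe these arrays only. A probe covers only 60 bases, so most sites in these transcripts were not searched.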
